A study of Arabidopsis thaliana with 12 samples.

How the data were processed

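Total RNA of Arabidopsis thaliana, ecotype Columbia 0, was measured on 12 expression arrays, 6 of wild type (WT) and 6 of the psan mutant, which lacks PSI-N, a small subunit of photosystem I encoded by the nuclear gene PSAN (AT5G64040). Groups and sample numbers 1 to 6 were taken from the sample titles. The values of each sample are called an array here, and whether samples shared a slide or filter is not given. The tissue, growth conditions, array type and origin of the numbered samples are not given in the sources used here. Nothing says that the samples came from separate plants, so p-values measure only the spread between these arrays, which may be technical.

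The deposited values were intensities on a linear scale for 3439 probes. How the authors scaled them is not given in the sources used here. The values themselves show a floor at exact 0, with 161 to 521 probes at 0 per array, and a ceiling just under 100 that 1 to 3 probes reached on each array. Array means lay between 0.834 and 0.980. The medians of the log2 values above 0 lay between -2.88 and -1.69, so the arrays were not equalised on their medians. For arrays, their number limits the precision.

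Of the 3439 probes, 692 carried 1 gene symbol in the platform annotation, 870 carried several and 1877 were unnamed here. Genes were named only from probes with 1 symbol. Of these, 690 matched a locus of the TAIR10.1 gene table, which was used for names only, and they covered 689 loci. AT2G25870 was the locus with 2 such probes. Where a gene had several probes, the probe with the highest mean over all 12 arrays stood for it.

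Choices named here as the analysis setting were made before the data were examined. Arrays were quantile normalised, zeros were then left out array by array, and log2 values were fitted with limma 3.58.1 (lmFit and eBayes, two-sided, psan minus WT) in R 4.3.3. P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Intensities are given as deposited, and log2 fold changes after normalisation unless stated otherwise, so the 2 need not match. A probe was tested when at least 1 array of each group was above 0, which left 3376 probes. PSAN was also compared with an exact permutation test of the 6 against 6 values. Named genes were PSAN, then the 12 largest rises and 12 largest falls in log2 fold change among single-gene probes past the threshold, then for each gene list up to 4 members past the threshold or, failing that, the 2 with the smallest p as values. In all, 17 lists of photosynthesis, plastid, stress and other-tissue genes had been fixed. Lists with at least 3 measured genes were tested with limma's camera at its preset correlation of 0.01, with an estimated correlation and with fry. Figures were drawn with matplotlib 3.10.9.

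Samples of a group were compared by the correlation of their deviations from the group mean over 2243 probes above 0 on all arrays. In both groups, numbers 1 and 2, 3 and 4, and 5 and 6 were each other's closest match. Each of these 6 pairs correlated above every other pair of its own group. Of the 6, 5 also lay above the highest other pair of either group (r = 0.0928, in WT), with a highest r of 0.601. Psan 1 and 2, with r = 0.0331, lay above the other psan pairs (at most -0.144) but below that value. Such pairs may be repeat measurements of 1 sample, so every leading count is also given with the pairs averaged, as 3 against 3. A pair at 0 on both arrays gave no value for that probe, which leaves fewer than 3 in its group. Averaging was among the alternatives fixed in advance.

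The fit was tested on 20 simulated datasets of 2980 probes for psan against WT, drawn with the real means and spreads and with 200 probes changed. With independent arrays it recovered on average 36.3% of probes changed 2-fold and 80.8% of those changed 4-fold, and 4.30% of its calls were false. With arrays correlated in pairs at the consensus value of 0.606, 34.9% of the calls over 12 arrays were false, against 4.22% with averaged pairs. Averaged pairs then recovered 2.25% of the 2-fold and 42.7% of the 4-fold changes. With paired arrays and no probe changed, the fit over 12 arrays made 10.2 false calls on average and at most 22, and averaged pairs made 0. Probes were drawn independently and without an effect of the probe number, and a false share depends on how many probes change. These values therefore do not carry over to the real counts.

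Alternatives fixed in advance were the values as deposited, median centring, cyclic loess, leaving out the dimmest 25% of probes, an offset, the sample number as a block, eBayes with trend and robust, each array left out, averaged pairs, other thresholds and other set tests. After the data were seen, a correction for the probe number was added, alone and with averaged pairs. It removes, from each array, row and column effects of the probe number within a repeating period of 288 numbers. Further added alternatives averaged only those 5 pairs, used the pair as a random block, left out WT arrays 1 and 2, used an offset from values above 0, and left zeros out before normalisation.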

Results

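The series held 12 arrays, 6 of WT and 6 of the psan mutant of Arabidopsis thaliana, and asked which transcripts differ when the photosystem I subunit PSI-N is missing. Each array gave 1 intensity for each of 3439 probes. The share of probes at 0 was 4.68% to 15.2% on the WT arrays and 6.19% to 10.8% on the psan arrays.

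PSAN (AT5G64040), the gene of the missing subunit, was low on every psan array. Its deposited intensity was 6.30 ± 1.27 (SD, n = 6) in WT and 0.176 ± 0.0697 (SD, n = 6) in psan. The WT arrays lay between 4.40 and 7.77 and the psan arrays between 0.0681 and 0.243, so the groups did not overlap. After normalisation, the log2 fold change was -5.46 with a standard error of 0.34, or 44.2-fold lower. As deposited, it was -5.26. The limma adjusted p after normalisation was 2.27e-06, the smallest of all probes. An exact permutation test of the 6 against 6 values gave a two-sided p of 0.00216, the smallest that test allows. With averaged pairs the limma adjusted p was 0.0338 and the exact p was 0.1, the smallest that 3 against 3 allows. The probe's place relative to the disrupted part of the gene is not given in the sources used here.

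**Figure D1:**
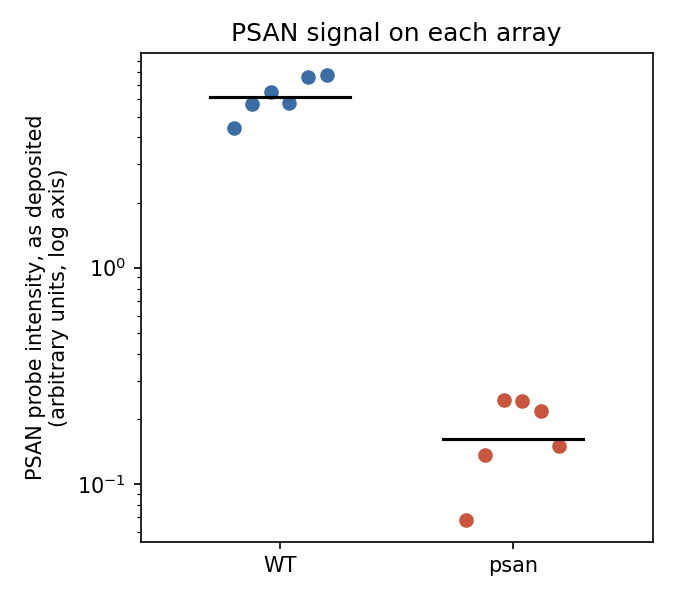
Deposited intensity of the PSAN probe (log axis, arbitrary units) on each of the 6 WT and 6 psan arrays, as points, with the geometric mean of each group as a line. The WT arrays lie between 4.40 and 7.77 and the psan arrays between 0.0681 and 0.243.

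The comparison of all genes asked which transcripts were higher or lower in psan. Among the single-gene probes, the largest rises were of APTX (aprataxin, a DNA repair protein) with a log2 fold change of 5.50 ± 1.03 (SE), AT5G52970 with 4.56 ± 0.96 and AT3G25680 with 3.98 ± 0.88. All 3 were at 0 on some WT arrays, and AT3G25680 had 4.70 without WT array 4. APTX was above 0 on only 2 of the 6 WT arrays, so the size of its rise is not fixed: its log2 fold change was 3.18 without WT array 3, 7.81 without WT array 1, 3.58 with an offset and 8.05 as deposited. AT5G52970 was above 0 on only 2 WT and 2 psan arrays. It had 3.34 without WT array 5 and 5.77 without WT array 6, and its call did not hold without psan array 1 (adjusted p = 0.0800) or 2 (0.116). It also did not pass with cyclic loess (log2 fold change 1.41, adjusted p = 0.143), an offset (0.41, adjusted p = 0.399), eBayes with trend and robust (0.212), median centring (0.0504) or zeros left out first (0.0523). The largest falls after PSAN were of AT2G06040 with -3.29 ± 0.72, AT4G16060, at 0 on 2 psan arrays, with -3.05 ± 0.51 and AT1G03810 with -2.87 ± 0.40. CYN, the cyanase that breaks down cyanate, fell by 2.23 ± 0.19 on the log2 scale after normalisation. Its deposited intensity went from 2.24 ± 0.159 (SD, n = 6) to 0.553 ± 0.0949 (SD, n = 6), a log2 fold change of -2.03 as deposited.

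Of the genes that rose without a 0 on any array, AT5G39980, which encodes a pentatricopeptide repeat protein, went from a deposited intensity of 0.104 ± 0.0441 (SD, n = 6) to 1.76 ± 0.878 (SD, n = 6). Its log2 fold change was 4.05 as deposited and 3.53 after normalisation, the latter with a limma adjusted p of 4.96e-05. AT4G35660 also had a log2 fold change of 3.53 but a standard error of 1.01, with 2.72 without WT array 2 and 1.81 without WT arrays 1 and 2 (adjusted p = 0.000434). It did not pass as deposited (0.0590), with median centring (0.0833) or with cyclic loess (0.0535). AT5G40030 and AT5G63390 had log2 fold changes of 3.72 and 2.93. AT5G40030 had 3.06 without WT array 5 or 6, 4.33 without WT array 2, 5.05 without WT arrays 1 and 2 and 1.94 with an offset. AT5G63390 did not pass with cyclic loess (log2 fold change 3.40, adjusted p = 0.0526) or zeros left out first (3.77, adjusted p = 0.0537). It had 4.17 as deposited and 2.15 with the probe number corrected, and passed with both. The remaining rises were of AT2G47680 (3.82), AT3G56330 (3.08), PRA1.B6, a prenylated Rab acceptor (2.98), AT1G75260 (2.97) and AT3G60590 (2.86). Each was at 0 on some WT arrays, and AT1G75260 also on 2 psan arrays. AT2G47680 had 2.61 without WT array 3, 4.61 without WT array 5 and 1.94 with an offset, and AT3G60590 had 2.23 without WT array 4. AT1G75260 had 2.095 without WT array 6 and 3.65 without WT array 4. AT1G75260 did not pass without psan array 5 (adjusted p = 0.0512) or 6 (0.0526), with cyclic loess (log2 fold change 1.70, adjusted p = 0.0932), with an offset (1.06, adjusted p = 0.109) or with zeros left out first (1.93, adjusted p = 0.0615).

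AT2G39000, an acetyltransferase gene, had a log2 fold change of -2.25, AT2G02590 of -2.15 and AT4G34310 of -2.13. CBL, cystathionine beta-lyase of methionine synthesis, had -2.13. AT1G79080, AT4G38040 and AT4G37420 had -2.66, -2.64 and -2.32, and each was at 0 on some psan arrays. As deposited, CBL and AT4G37420 did not pass (adjusted p = 0.126 each). None of the 24 named rises and falls, PSAN included, turned its sign under 6 alternative scalings and corrections.

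With averaged pairs, 3 of the 12 rises (AT5G39980, AT3G56330 and PRA1.B6) and 7 of the 12 falls (PSAN, AT2G06040, AT4G16060, AT1G03810, AT2G39000, CYN and AT4G34310) stayed past the threshold. For AT3G56330 and PRA1.B6, WT arrays 1 and 2 were both at 0, so that pair gave no value and WT had fewer than 3. For AT3G56330, the pair of WT arrays 3 and 4 rested on WT array 3. AT2G06040 passed with all pairs averaged (adjusted p = 0.0413), but not with only the 5 closer pairs averaged (0.0793) or the pair as a random block (0.110). With the probe number corrected over 12 arrays, 10 rises and 11 falls passed, the exceptions being AT5G40030 (adjusted p = 0.0602), AT4G35660 (0.0533) and AT1G79080 (0.0517). With both, only PSAN passed.

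**Figure D2:**
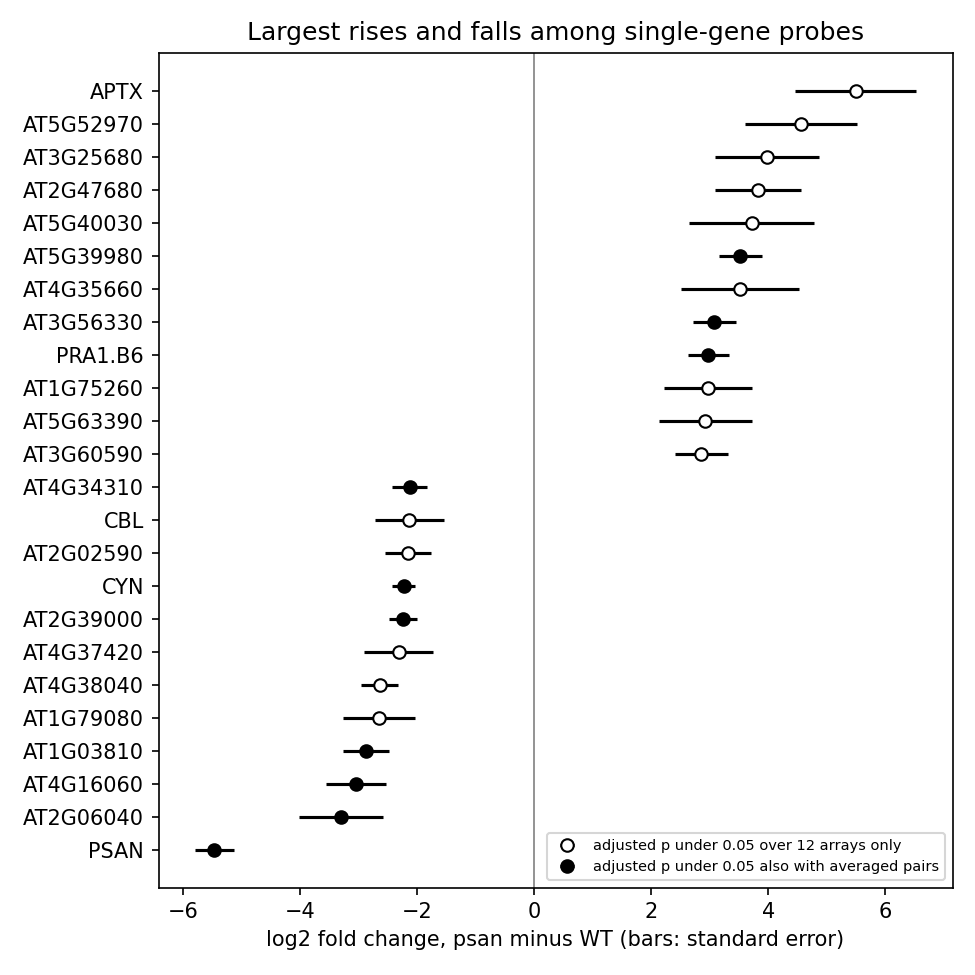
Log2 fold change, psan minus WT, with its standard error, of the 12 largest rises and 12 largest falls among single-gene probes past the limma threshold over 12 arrays. Filled points, 3 rises and 7 falls, also passed with averaged pairs.

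Over all probes, 1008 of 3376 passed over the 12 arrays, 482 higher and 526 lower in psan. Of these, 202 were single-gene probes, 106 higher and 96 lower, or 27 with averaged pairs, 15 higher and 12 lower. With averaged pairs, 142 of all probes passed, 79 higher and 63 lower, all of them among the 1008 and in the same direction. With the probe number corrected, 800 passed, of which 612 were among the 1008, and 7 of the 1008 turned sign. With averaged pairs as well, 6 passed. The split between higher and lower varied with the probe number, as given below, and depended on the scaling. On the values as deposited, 747 were higher and 254 lower, and with each array centred on its median, 338 were higher and 675 lower.

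Before normalisation, the median log2 fold change over all probes was 0.46, or 0.26 without WT arrays 1 and 2. The array medians of log2 values averaged -2.48 ± 0.29 (SD, n = 6) in WT and -1.81 ± 0.09 (SD, n = 6) in psan. After quantile normalisation the median fold change was -0.015. The shift was not the same for all probes, since it was 0.71 in the sixth 10% of the probes by brightness and 0.018 in the brightest 10%.

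On the first principal component, with 40.6% of the variance, all WT arrays lay on one side and all psan arrays on the other. The next component, with 20.6%, set WT arrays 1 and 2, at -31.7 each, apart from the other WT arrays, at 14.1 to 16.2. Psan arrays 3 and 4 lay on the same side, at -13.0 and -14.9, with the other psan arrays at 4.68 to 10.2. Without WT arrays 1 and 2, 1011 probes passed, of which 836 were among the 1008.

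**Figure D3:**
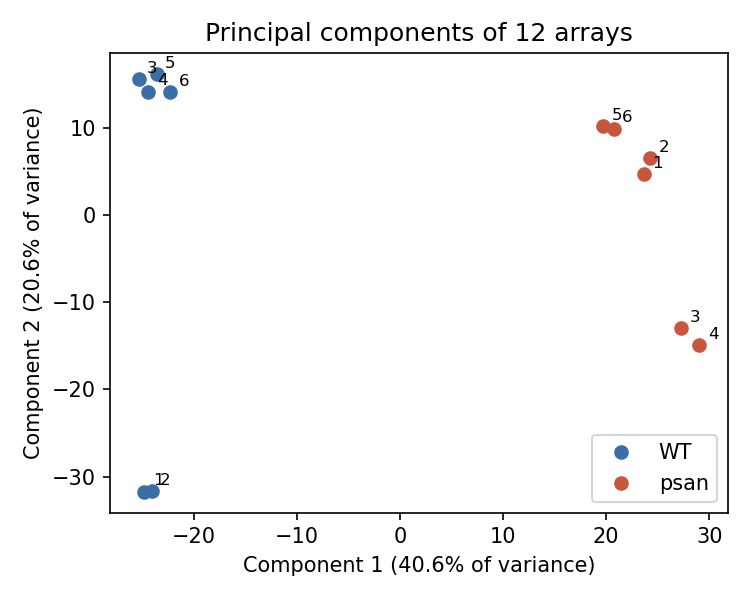
Scores of the 12 arrays, numbered by sample, on the first 2 principal components of normalised log2 values. WT lies left and psan right, and WT arrays 1 and 2 lie at -31.7 on the vertical axis.

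The gene lists asked whether photosynthesis and plastid genes moved together. Of the plastid ribosomal protein list, 5 of 41 genes were tested through a single-gene probe, and AT1G64510 (PRPS6) fell, with a log2 fold change of -1.79 ± 0.40 (SE) and a limma adjusted p of 0.00539. As deposited it did not pass (-1.17, adjusted p = 0.0981). The other 4 did not pass: AT3G54210 (PRPL17) had -0.57, AT1G29070 (PRPL34) had -0.67, AT4G01310 (PRPL5) had 0.11 and AT3G13120 (PRPS10) had 0.08, which turned to -0.16 with median centring and -0.35 with the probe number corrected. Adjusted over the list alone, 2 passed, PRPS6 and PRPL17. AT3G54210 passed with median centring (-0.98, adjusted p = 0.00516), the dimmest 25% of probes left out (0.0368), eBayes with trend and robust (0.0391), zeros left out first (0.0417) and without WT array 5 (-0.69, adjusted p = 0.0246). AT5G65220 (PRPL29) was listed at 0 on all 12 arrays. The median was -0.57, but -0.00060 as deposited and -0.29 without psan array 4, and camera gave an adjusted p of 0.474, or adjusted p = 0.375 with an estimated correlation.

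Of the photosystem II subunit list, 3 of 15 genes were tested. PSB27, a lumen protein of photosystem II assembly and repair, rose by 0.76 ± 0.22 (SE) on the log2 scale, with a limma adjusted p of 0.0217, and it was also the 1 gene that passed adjusted over the list alone. It did not pass with median centring (0.24, adjusted p = 0.406) or without WT arrays 1 and 2 (0.66, adjusted p = 0.0680). PSBY had 0.18 and PSBW had -0.06, and neither passed. The sign of PSBY turned with median centring (-0.52, against 0.16 as deposited), which moves all probes of an array alike relative to the deposited values. That of PSBW turned with cyclic loess (0.15) and with the probe number corrected (0.49). The list median was 0.18, from 0.073 without psan array 4 to 0.32 without WT array 2, 0.50 without WT arrays 1 and 2 and 0.71 with the probe number corrected. For this list camera gave an adjusted p of 0.474, or adjusted p = 0.375 with an estimated correlation.

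Fry, which asks whether a list's own genes move one way on balance, gave an adjusted p of 0.00887 for the ribosomal list and 0.0184 for the photosystem II list over 12 arrays taken as independent. With averaged pairs these were 0.0383 and 0.121, and with the pair as a random block 0.0843 and 0.0935. Fry's test for change in either direction, over 12 arrays, gave 0.171 and 0.537. Fry sets a list against a fold change of 0, whose place depends on the scaling, and these values are from quantile-normalised data. The list medians given above moved with the scaling. As 1008 of 3376 probes passed over 12 arrays, the 1 passing member in each list does not stand out. No member of either list passed with averaged pairs.

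The other lists had too few measured genes for a list test. In the Calvin cycle list, SBPASE, sedoheptulose bisphosphatase, fell by 1.26 ± 0.23 (SE) on the log2 scale with a limma adjusted p of 0.00158, and PRK, phosphoribulokinase, had 0.52 and did not pass, with -0.049 under median centring and 0.89 without WT arrays 1 and 2, where it passed (adjusted p = 0.0308). In the antioxidant list, AT3G52960, a plastid peroxiredoxin, rose by 1.14 ± 0.40 (SE) with a limma adjusted p of 0.0473, and NTRC had 0.27 and did not pass. Leaving out any 1 of 9 of the 12 arrays ended the AT3G52960 call (adjusted p from 0.0526 to 0.0940), as did leaving out WT arrays 1 and 2 together (0.152), median centring (1.09, adjusted p = 0.0749) and zeros left out first (1.19, adjusted p = 0.0552). With the probe number corrected, AT3G52960 did not pass (log2 fold change 0.50, adjusted p = 0.199) and NTRC did (0.94, adjusted p = 0.0132), as it did on the values as deposited (0.91, adjusted p = 0.0170). With averaged pairs neither SBPASE (adjusted p = 0.0688) nor AT3G52960 (adjusted p = 0.243) passed. Adjusted over each list alone, 1 gene passed in each of these lists, SBPASE and AT3G52960.

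LHB1B2 of the LHCII antenna list had a log2 fold change of -0.32, or 0.23 with the probe number corrected, and CHLM of the chlorophyll synthesis list had -0.33, or 0.37 as deposited. Neither passed, but CHLM did without WT arrays 1 and 2 (-0.71, adjusted p = 0.0200). The lists of photosystem I core subunits, LHCI antenna, electron carriers, ATP synthase, carotenoid synthesis, photorespiration, starch metabolism, plastid proteases and chaperones, plastid protein import, high light and senescence, and seed and root markers had no single-gene probe and were not analysed here.

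The fold change also followed the probe number. Along the numbers it correlated with itself at a distance of 288, across probes, with r = 0.224, against at most 0.0697 in 1000 shuffles of the numbers. The distance of 288 was chosen from these same values, as the multiple of 12 with the highest correlation among those tried, so this r is a selected maximum. The median per bin of 12 numbers ran from -0.75 to 0.58. The direction of the calls over 12 arrays went with it. In the bin with the lowest median, 3 probes were called higher and 63 lower. In the bin with the highest, 39 were called higher and 3 lower.

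**Figure D4:**
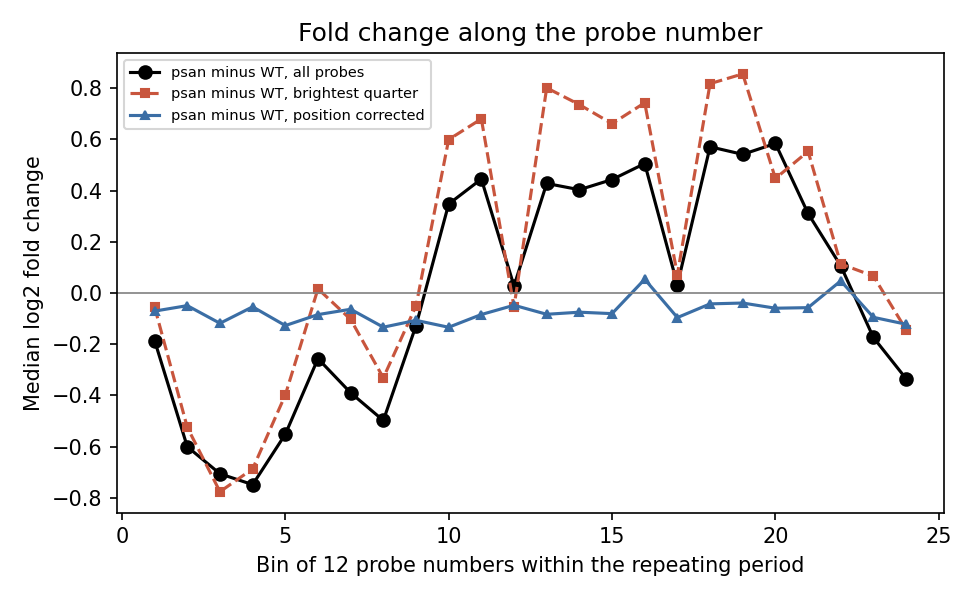
Median log2 fold change, psan minus WT, in 24 bins of 12 probe numbers within the repeating period of 288 numbers, for all probes, for the brightest 25% and after position correction. All probes range from -0.75 to 0.58 over the bins.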

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

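Among 103 groups of arrays tested for a single array far from the others, 3 stood out, where chance gives about 5.15. The normalised log2 signal of AT3G25680 on psan array 2 was -5.14, against -2.49 to -1.15 on the other psan arrays, a gap of 0.664 of the range. That of AT5G63390 on psan array 4 was 0.71, against -2.61 to -1.42, a gap of 0.643. That of CBL on WT array 2 was -2.73, against -1.23 to -0.33, a gap of 0.627.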

How the results depend on the processing

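PSAN kept its direction and stayed past the threshold under all 26 alternatives run, with log2 fold changes from -5.94 to -4.83 and limma adjusted p from 1.71e-08 to 0.0338. The count of 1008 probes fell to 142 with averaged pairs and to 585 at an adjusted p under 0.01. Under alternatives chosen after seeing the data it was 800 with the probe number corrected, 612 of them among the 1008, and fell to 294 with only the 5 closer pairs averaged, to 492 with the pair as a random block, and to 6 with averaged pairs and the probe number corrected. Averaging leaves fewer samples. Leaving out each array gave 889 to 978. The replicate number as a block gave 896. Numbers paired the samples weakly at most, since deviations of same-numbered arrays correlated from -0.155 to 0.228 and 4 of 12 arrays matched their own number best. Deviations of WT arrays 5 and 6 correlated with those of psan arrays 5 and 6 with r from 0.179 to 0.228. No fit used pairs of numbers shared across the groups as a block. The block changed neither list nor the PSAN call, but APTX (adjusted p = 0.0856), AT5G52970 (0.0990), AT1G79080 (0.0553), AT4G37420 (0.0681), PSB27 (0.0684) and CRR21 (0.0551) did not pass with it, in a model with fewer degrees of freedom. The photosystem II list median, 0.16 as deposited, turned to -0.52 with median centring, which takes the difference of the array medians from all probes alike. It was 0.50 without WT arrays 1 and 2. With fry, medians of -0.57 and 0.18 passed, a test of other scope. With fry on averaged pairs, run after seeing the data, only that of -0.57 did. The median over all probes, 0.46 as deposited and 0.26 without WT arrays 1 and 2, was -0.015 with quantile normalisation, -0.20 with median centring and -0.020 with cyclic loess, as these scalings construct. It was -0.064 with the probe number corrected, -0.048 with an offset of values above 0 and -0.063 with zeros left out first. The 23 other rises and falls gave 517 values on the same side of the threshold, 77 that no longer passed and 0 that turned sign. The 30 remaining named genes and probes gave 670 on the same side, 76 that no longer passed, 10 that newly passed and 23 that turned sign, in 9 genes. Of these 9, only NdhS had passed, and it turned with median centring alone (-0.041), as did PSBY (-0.52) and PRK (-0.049). PSBW had 0.15 with cyclic loess, 0.49 with the probe number corrected, with or without averaged pairs, 0.028 without WT arrays 1 and 2, and -0.14 to 0.061 leaving out each array. LHB1B2 had 0.23 with the probe number corrected, with or without averaged pairs, and 0.15 without WT arrays 1 and 2. CHLM had 0.37 as deposited. AT3G13120 had -0.16 with median centring, -0.35 with the probe number corrected, with or without averaged pairs, and -0.087 to 0.26 leaving out each array, where AT4G01310 had -0.038 to 0.32. NdhN had 0.51 as deposited, 0.15 without WT arrays 1 and 2 and -0.45 to 0.11 leaving out each array. The offset fixed in advance was not run, because the 5th percentile of all values is 0. No background signal was used here, so dim probes have no known limit.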

Other observations

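The genes in this paragraph and the next were chosen after their values were seen. AT5G58330, the plastid NADP-dependent malate dehydrogenase that exports reducing power, rose from a deposited intensity of 1.04 ± 0.286 (SD, n = 6) to 4.09 ± 0.337 (SD, n = 6). Its log2 fold change was 2.02 as deposited and 1.96 after normalisation, the latter with a limma adjusted p of 1.14e-05, and 0.0377 with averaged pairs. AT1G22700 (PYG7), an assembly factor of photosystem I, had a log2 fold change of 2.16 with a limma adjusted p of 0.00129, and 0.0413 with averaged pairs. Its deposited intensity was low in WT, at 0.0412 ± 0.0300 (SD, n = 6) with a 0 on 1 array, and 0.338 ± 0.0751 (SD, n = 6) in psan. As deposited, its log2 fold change was 2.92. With averaged pairs and the probe number corrected, neither AT5G58330 nor AT1G22700 passed (adjusted p = 0.0652 each). AT1G74470, geranylgeranyl reductase of chlorophyll synthesis, rose by 0.86 on the log2 scale (0.28 with median centring, adjusted p = 0.352) and AT5G17630, a plastid sugar phosphate translocator, by 2.06. LPA19, a photosystem II assembly factor, had a log2 fold change of -1.77 (-1.09 with the probe number corrected, adjusted p = 0.0122). GLDH, the last enzyme of ascorbate synthesis, fell by 1.35 on the log2 scale (0.70 with the probe number corrected, adjusted p = 0.0655) and CUTA by 1.28. These last 5 did not pass with averaged pairs.

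Of 5 genes of the plastid NDH complex and its accessory factors, NdhS (0.94), CRR41 (1.65) and CRR21 (1.37) passed over 12 arrays, and NdhN (-0.14, but 0.51 as deposited) and PIFI (-1.04) did not. NdhS had 0.63 as deposited and -0.041 with median centring, which moves all probes of an array alike relative to the deposited values. CRR21 did not pass without WT array 6 (adjusted p = 0.0502), without WT arrays 1 and 2 (0.0561) or with the probe number corrected (log2 fold change 0.66, adjusted p = 0.261), where PIFI did (-1.68, adjusted p = 0.0289). None of the 5 passed with averaged pairs. The 2 probes of AT2G25870 went opposite ways, with log2 fold changes of -0.89 and 1.59 (2.18 without WT arrays 1 and 2), each past the limma threshold over 12 arrays, but the lower one not as deposited (-0.39, adjusted p = 0.334). Among unnamed probes, probe 910 was 31.5 ± 6.86 (SD, n = 6) in WT and 62.0 ± 6.0 (SD, n = 6) in psan. Probe 4141 was at the ceiling near 100 on all 6 WT arrays and between 31.3 and 70.7 on the psan arrays.

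Tests of the mutant response by position, of both explanations of the higher psan median and of an exchanged sample were chosen only after the result was seen, as were the shuffles of the brightest probes, the profile within psan, the comparison of the dimmest probes with the middle ones and the correlation of WT arrays 1 and 2 in bright probes. Of the 100 splits of the 12 arrays drawn from 462, 1, the real one, called as many as 1008 probes, and the highest other split called 1. That would argue against chance if the 12 arrays were independent. They may be repeat measurements in pairs, which these splits break up, so chance is not excluded. With averaged pairs, 1 of 10 splits, the real one, called 142 probes and the highest other called 0, but 10 splits cannot give a share under 0.05.

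The fold change repeated along the probe number. An uneven additive background would move dim probes more than bright ones. The spread of the bin medians was 0.507 in the brightest 25% of probes, against a 95th percentile of 0.268 in shuffles, and the dimmest minus the brightest 25% was -0.0142 (95% bootstrap interval -0.203 to 0.117), which argues against it as the whole cause. WT arrays 1 and 2 against the other WT arrays also gave a profile over position, of 0.155 against 0.117 in shuffles, and psan arrays 3 and 4 against 5 and 6 gave 0.284 against 0.109. Both were smaller than the 0.446 of psan against WT. Over the bins, the profile within psan correlated with that of psan against WT with r = 0.579, and the profile within WT with r = 0.106. Psan arrays 3 and 4 thus differed from 5 and 6 by a profile of partly the same shape as psan against WT. The profile of WT arrays 1 and 2 against the other WT arrays had little of that shape. These contrasts set unlike arrays apart, so they do not compare the groups. The profiles share arrays and these r have no interval here, so they do not decide between causes. A response of the mutant to genes placed together still cannot be told apart from an effect of the arrays. The profiles within a group were smaller, and how the samples were placed on slides or filters is not given.

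The psan arrays had higher medians before normalisation. One scale factor per array would shift all probes alike, but the shift was 0.52 in the dimmest 10% of the probes and 0.018 in the brightest, a difference of 0.504 (95% bootstrap interval 0.258 to 0.751), which argues against it. An additive background left in the psan arrays would give a difference of this sign, but it would also shift the dimmest probes the most. The median shift was 0.52 in the dimmest 10% and 0.71 in the sixth 10%. The dimmest probes lay -0.168 from the middle of the range (95% bootstrap interval -0.437 to 0.0828), so that point is undecided. The zeros leave this background open too. There were 213 to 371 probes at 0 per psan array, 499 and 521 on WT arrays 1 and 2, and 161 to 215 on the other WT arrays. An additive background left in psan would leave fewer zeros there. That was so against WT arrays 1 and 2, but not on the whole against the other WT arrays. A change in the mutant's RNA stays open and was not tested.

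WT arrays 1 and 2 stood apart from the other WT arrays. Their lowest PSAN intensity was 4.40, against at most 0.243 on the psan arrays, which argues against a mutant sample under a WT label. The spread of their difference from the other WT arrays was 1.12 times as large in the dimmest as in the brightest 25% of probes (95% bootstrap interval 0.972 to 1.28), which alone decides nothing. In the brightest 25%, differences of WT array 1 and of WT array 2 from separate pairs of the other WT arrays correlated with r of at least 0.845 (95% bootstrap interval 0.801 to 0.878), though they share no array. The spread there was 1.04, against 0.425 between WT arrays 3 and 4 and WT arrays 5 and 6. These values argue against weak signal of dim probes as the cause. Psan arrays 3 and 4 shared part of the split, since their deviations correlated with those of WT arrays 1 and 2 with r from 0.175 to 0.272. What set these arrays apart stays open, and no biological explanation was tested.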
